A study of Mus musculus with 24 samples.

How the data were processed

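Visium spatial transcriptomics was performed on 24 fresh frozen mouse brain sections, 12 from untreated control mice and 12 from mice given 6-hydroxydopamine (6-OHDA) on 1 side, at 0.6 µg/µL per the treatment protocol (the sample labels give 0.6 µg). The deposited values are UMI counts per gene and spot, that is, counts of distinct captured RNA molecules, for the spots that lay over tissue, with 1 table of counts per section and no pooling of sections. Per the submitters' processing notes, Space Ranger 1.3.1 was run on genome build mm10; the annotation release and any filter on genes are not given in the sources used here. Per the labels, tissue was permeabilized for 14 min and all sections belong to 1 batch. Each table held 32285 genes with their Ensembl identifiers and symbols, which were used as given, and the positions of the spots came from the deposited lists of array positions. No coordinates in the genome were used. How reads shared by near-identical gene copies were counted is not given in the sources used here, so values of genes with such copies (C4b, Ifit3, the haemoglobin genes) are uncertain.

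Groups and replicate numbers (1 to 12 in each group) were taken from the sample titles, and the slide from the section names. The 6 slides held 2 sections of each group each. The series description gives 3 mice per group and 4 levels per mouse, but the labels do not tie a section to a mouse. Sections were therefore the samples of the tests, with the slide as a block, and because several sections share an animal, p-values over sections are too small as statements about animals. Each test was set beside one on 3 sums against 3, in which the sections of 2 slides with neighbouring serial numbers (a slide pair) were summed within each group. Whether such a sum holds 1 animal is not known. No 2 sections had identical sums of counts.

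Regions were assigned without any gene of interest. Counts of 78 region marker genes were scaled to 10000 UMIs per spot, log-transformed, averaged with the neighbouring spots and standardized, giving 1 score per region and spot, and the 52646 spots of all sections were clustered on these scores by k-means (12 clusters, 20 restarts, fixed seed; Python 3.11.15, numpy 2.4.6, pandas 2.3.3). Clusters with a mean striatal score over 0.4 were called striatal, and ventral where the ventral striatal score was the higher one. Clusters with a cortical score over 0.5 were called cortical, and a cluster led by the white-matter score was called white matter. These score limits were set after the cluster scores had been seen and before any group was compared. The dorsal striatal cluster had Lrrc10b and Pde10a among its leading genes, the ventral one was led by Cartpt, Pdyn and Wfs1, and the white-matter cluster had Mal and Ermn among its leading genes. Of the 2 cortical clusters, that led by Slc30a3, Vip and Nrn1 had fixed cortical markers among its 10 leading genes and that led by Trbc2, Ighm and Myl4 had none. Of all spots, 2364 lay within 0.25 of the limit used when spots were gated on their striatal score. A spot can hold cells of several types, and no cell-type makeup was estimated. Marker genes of the regions are not reported as results.

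Counts were summed over the spots of each region in each section, and a section entered a regional test with at least 50 such spots, which left 7 control and 8 6-OHDA sections for the ventral striatum and all 24 sections for the other regions. Genes were filtered with filterByExpr at its default settings, scaled by TMM and tested with edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences between regions were tested as the treatment by region interaction with the section as a block. Log2 fold changes are 6-OHDA over control, standard errors were taken as the absolute log2 fold change over the square root of the F statistic, and CPM are relative to the TMM-scaled library size and given as mean ± SD over sections. Gene lists (35 lists for cell types, signalling and cell processes) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry; 2 of their genes, Clec7a and Septin4, had no row under those symbols. Depth, RNA quality and shares of spots were compared by two-sided permutation tests over sections, with groups exchanged within slides and 100000 resamples. Figures were drawn with matplotlib 3.10.9.

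The regions' markers, gene lists, tests and alternatives, and the rule for the genes named in the text, were fixed before the data were examined. For the striatum the rule takes the 10 genes with the largest log2 fold change in each direction, and for other comparisons the 5, among genes with an adjusted p under 0.05, a mean of at least 10 CPM and the same sign on all 6 slides (the 4 slides with ventral striatal sections of both groups for the ventral tests). On slide 6 only 6-OHDA section 11 had enough ventral striatal spots (60). With the slide as a block it carried no contrast between the groups. Region markers, predicted gene models and sex-linked genes are left out by the rule, and Penk, Drd2, Adora2a, Drd1, Tac1, Pdyn, Th, Gfap, Fos, Egr1, Arc and the members of a described gene list with the smallest adjusted p are added. As a check of the sections, the sex-linked genes were read once: Xist lay between 0 and 0.0559 CPM and Ddx3y between 27.8 and 50.1 CPM over the 24 sections.

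Replicate numbers were checked for pairing before the tests with them were compared. Deviations from the group means over 12840 genes correlated between control and 6-OHDA sections of the same number at 0.181 to 0.466 (12 pairs, median 0.323). For sections of different number the median was -0.0482. Sections of the same number also lay on the same slide, so this check cannot tell pairing by number from a shared slide. With the replicate number as a block in place of the slide, 52 genes were called in the striatum, 101 in the cortex, 134 in the dorsal striatum and 143 in the whole section.

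The tests were run on simulated counts drawn from the striatal means, dispersions and totals, with 200 genes changed by known folds. For the striatal test over sections, run on 12751 genes, 68.2% of genes changed 1.25-fold, 98.5% of those changed 1.5-fold and 100% of those changed 2-fold were recovered, with 5 false calls among 182. For 3 sums against 3 the shares were 52.2%, 92.5% and 100% (12838 genes), and with the slide pair as a block 49.3%, 94.0% and 100%. For the interaction of striatum and cortex, run on 12703 genes, they were 40.3%, 88.1% and 98.5%, with 11 false calls among 162, over the nominal 5%. In a simulated test of gene lists, a list of 30 genes shifted by 0.3 (log2) was called and 0 of 34 unshifted lists were. The simulation held no differences between slides or animals and no correlation between genes, so recovery in the real data may be lower, above all for sums without a block.

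Alternatives fixed in advance were DESeq2 1.42.0 as the test, its size factors in edgeR, limma voom with the slide as a random block, no slide block, the replicate block, sums per slide or slide pair, no low-count filter or a mean of at least 10 CPM, leaving out mitochondrially encoded genes, each slide left out in turn, interior spots, gated spots, spots with at least 1000 UMIs, 10 or 14 clusters, the 50% of striatal spots of each section with the lowest white-matter marker share, and striatal sums thinned to 2110255 UMIs. Leaving out the 4 sections with over 150 spots under 1000 UMIs (control sections 1 and 2, 6-OHDA sections 2 and 5) and the 2 tests with the slide pair within group as a random block were added after seeing the data. An asymmetry between left and right striatum was not computed, because each section held 1 hemisphere.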

Results

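Gene expression was mapped in brain sections of adult C57BL/6J mice with the Visium assay, in which a frozen section lies on a slide covered with barcoded spots, each capturing polyadenylated RNA from a small area of tissue. One group had received a low dose of 6-hydroxydopamine (6-OHDA), a toxin that kills dopamine neurons, in the medial forebrain bundle of 1 side, the tract through which dopamine axons reach the striatum. The other group was untreated. The 12 control and 12 6-OHDA sections, from 3 mice per group according to the series description, lay on 6 slides with 2 sections per group on each. The labels do not tie sections to animals and do not say whether a section came from the injected side. The comparisons ask which genes differ in the striatum between the groups, and whether they differ in the tissue around it. The loss of dopamine input itself was not measured in these data.

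The sections held 1760 to 2587 spots and 15981614 to 36230781 UMIs each, with section medians of 8571 to 16741 UMIs and 3364 to 5174 genes per spot. Of all 52646 spots, 11724 were assigned to the dorsal striatum, 2806 to the ventral striatum, 21652 to the cortex and 4484 to white matter. The striatum gave 256 to 957 spots and 2110255 to 11303707 UMIs per section. It took 28.0% ± 10.1 of spots in control and 27.9% ± 7.52 in 6-OHDA sections (mean ± SD, n = 12 each), the cortex 41.5% ± 3.89 and 41.2% ± 4.39, white matter 7.80% ± 3.95 and 9.06% ± 3.93, and the ventral striatum 6.11% ± 5.44 and 5.15% ± 4.81. Two-sided permutation tests within slides found none of these 4 shares different (p = 0.979, 0.831, 0.371 and 0.367, adjusted p from 0.741 to 0.979). The sections in these tests share animals.

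**Figure D1:**
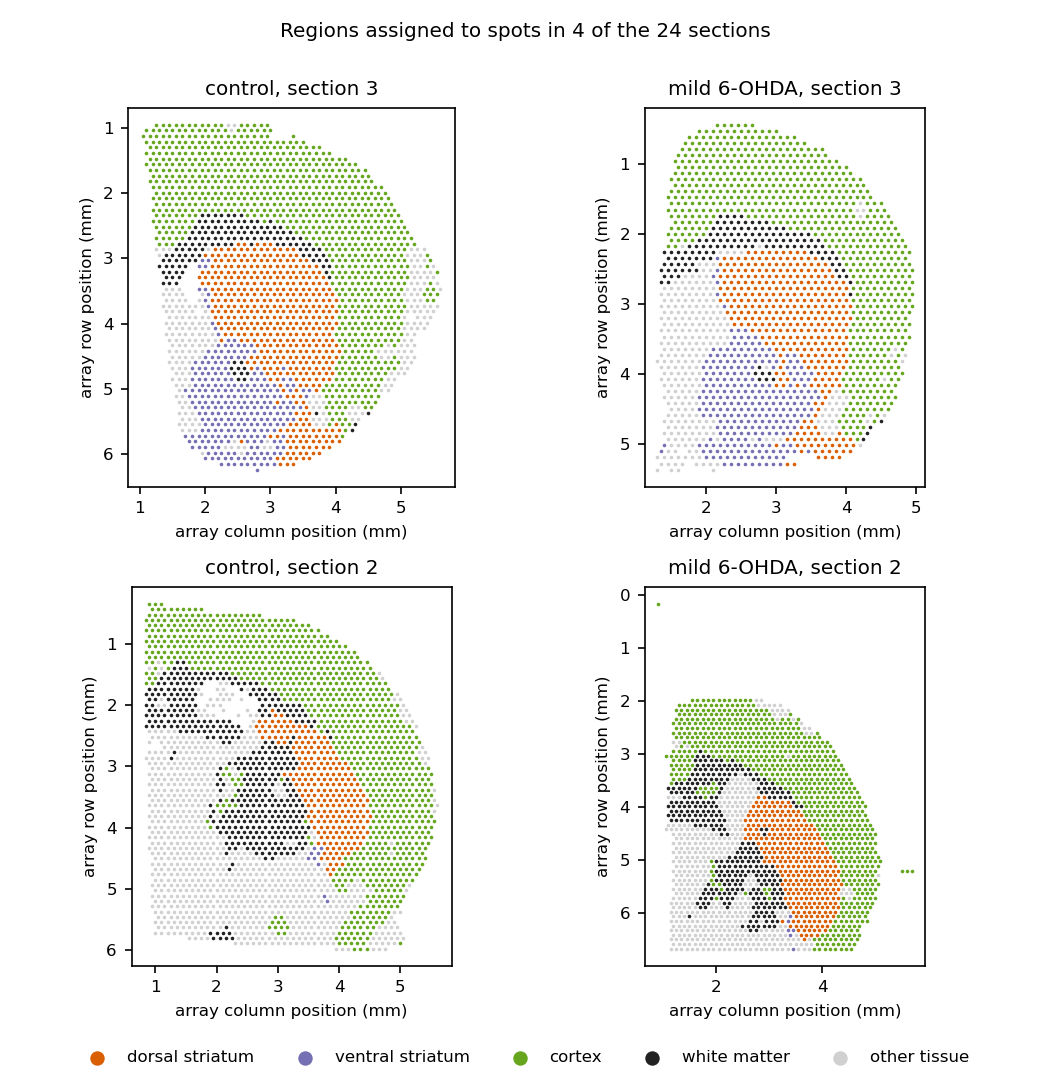
Regions assigned to the spots of 4 sections, control sections 3 and 2 and 6-OHDA sections 3 and 2, drawn by array position in mm along the columns and rows of the spot grid. Each point is 1 spot and its colour gives the region; the ventral striatum took 272 and 274 spots in sections 3 (control, 6-OHDA) and 9 and 6 in sections 2.

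In the striatal spots, section medians averaged 10268 ± 1960 UMIs per spot in control and 10502 ± 2528 in 6-OHDA sections, with 3679 ± 467 and 3705 ± 597 genes per spot. Mitochondrially encoded genes took 15.5% ± 0.838 and 15.7% ± 1.47 of the UMIs of a striatal spot (section medians, n = 12 each). Permutation tests within slides found none of the 3 measures different (p = 0.809, 0.906 and 0.653, adjusted p = 0.906 for each).

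In the striatal spots, immediate early genes, which neurons switch on quickly after stimulation, led the genes that fell in the 6-OHDA sections. Nr4a1, an orphan nuclear receptor, fell by 1.28 on the log2 scale (standard error 0.16), from 76.7 ± 22.9 CPM in control to 32.8 ± 21.2 CPM in 6-OHDA sections (mean ± SD, n = 12 each), and was lower on all 6 slides. Egr1, a zinc-finger transcription factor, fell by 0.47 (standard error 0.06), from 247 ± 36.6 to 178 ± 30.7 CPM. Tiparp, which encodes a mono-ADP-ribosyltransferase, fell by 0.59, Dusp6, a phosphatase that switches off the kinase ERK, by 0.52, and Fosl2, a partner in the AP-1 transcription factor, by 0.50. Smaller decreases were found for Id1, which blocks DNA binding of other transcription factors (-0.40), the clock gene Per1 (-0.37), Rgs2, which ends G-protein signals (-0.37), the mitochondrial carrier gene Slc25a25 (-0.37) and the phosphatase gene Dusp14 (-0.36).

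Among the genes that rose, Rasl11b, a small GTPase of the Ras family, was higher by 0.64 (standard error 0.10), with 32.8 ± 10.2 CPM in control and 50.8 ± 16.2 CPM in 6-OHDA sections. Mt2, a metal-binding metallothionein abundant in astrocytes, rose by 0.37 (standard error 0.08), from 230 ± 43.1 to 296 ± 42.6 CPM. Glial genes among the others were Tspan2, a tetraspanin of oligodendrocytes (0.32), Megf10, an engulfment receptor of astrocytes (0.31), and Ptgds, the brain's prostaglandin D synthase (0.30). Kndc1 (0.36), Arrdc3 (0.36), Sox12 (0.36), Gprc5b (0.33) and Tmem88b (0.31) complete the list of 10, each higher on all 6 slides. Megf10 stood at -0.05 when all sections were thinned to equal totals.

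Together, 54 of 12838 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 24 higher and 30 lower, and 34 of them also met the limits on level and on sign. Several sections share an animal and the labels do not tie sections to animals, so these p-values are too small: with 3 sums against 3, edgeR called 0 genes (569 at an unadjusted p under 0.05; DESeq2 was not run on these sums), and with the slide pair as a block 22. Every slide moved the count, which was 27, 137, 20, 23, 22 and 29 without slides 1 to 6, and 14 without the 4 sections rich in spots of few UMIs. Higher genes made up 6, 65, 3, 4, 5 and 11 of these calls without slides 1 to 6, 2 of those without the 4 sections, and 0 of the 9 calls without a block.

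**Figure D2:**
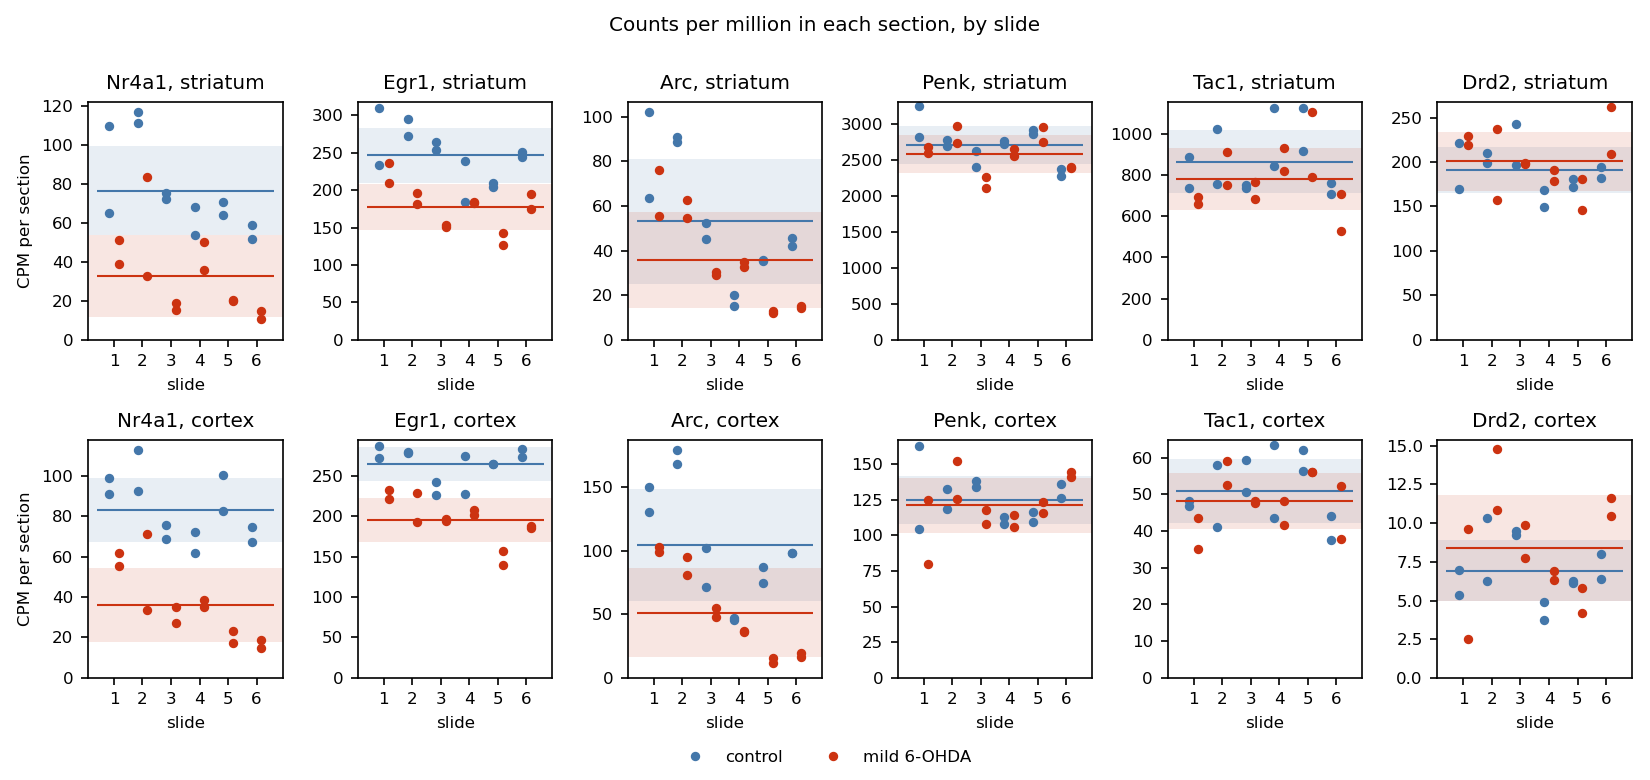
CPM in each section for 6 genes in the striatum (top) and cortex (bottom), by slide, with control sections in blue and 6-OHDA sections in red; lines are group means and bands 1 SD (n = 12 each). The slide means of Nr4a1 and Egr1 lie lower in the 6-OHDA sections on all 6 slides in both regions, while Penk, Tac1 and Drd2 overlap between the groups.

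None of 8 other genes fixed in advance passed the test in the striatum. The labels do not name the injected side, so these values do not measure the extent of dopamine loss. Penk, the enkephalin precursor of indirect-pathway projection neurons, stood at 2713 ± 267 CPM in control and 2591 ± 262 CPM in 6-OHDA sections, a log2 difference of -0.06 (standard error 0.05). Tac1, the substance P precursor of direct-pathway neurons, stood at 865 ± 152 and 780 ± 151 CPM, with a difference of -0.15 (standard error 0.07) that was below 0 on all 6 slides. The differences were 0.07 for the dopamine receptor gene Drd2, 0.04 for Drd1, 0.14 for the adenosine receptor gene Adora2a, -0.04 for the dynorphin precursor Pdyn and 0.02 for Gfap, an intermediate filament of astrocytes. Th, the rate-limiting enzyme of dopamine synthesis, had 9.06 ± 1.85 CPM in control and 9.27 ± 2.80 CPM in 6-OHDA sections. Adjusted p for these 8 genes lay between 0.242 and 0.987 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment); these differences were smaller than the smallest fold tested on simulated counts. The sign of Th, Pdyn, Gfap, Drd1 and Drd2 changed under at least 1 other setting.

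Of the 35 gene lists, the immediate early genes moved furthest. Of 23 measured members, 8 fell over all genes tested and 13 adjusted over the list alone, none rose, and the median log2 fold change was -0.36. Egr2 fell by 1.03, Nr4a3 by 0.86 and Junb by 0.44, beside Nr4a1, Egr1, Dusp6, Fosl2 and Per1. Arc, whose product works at synapses, and Fos did not pass, with -0.57 (standard error 0.16) and -0.36 (standard error 0.19). Camera with the preset correlation gave a Benjamini-Hochberg adjusted p of 4.8e-14 for the list, with adjusted p = 0.0229 with an estimated correlation and 0.00063 by fry, which asks whether the genes move on balance 1 way. The list's median lay between -0.369 and -0.147 in the 3 slide pairs.

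By the p of camera, oligodendrocyte genes came next. Of 15 measured members 14 had a positive difference, 1 rose (Tspan2) and 6 adjusted over the list alone, with a median of 0.20; Fa2h and Aspa, genes of myelin lipid metabolism, stood at 0.28 (standard error 0.08) and 0.29 (standard error 0.09). The list's adjusted p was 6.0e-07 with the preset correlation and 0.79 with an estimated correlation. Markers of the white-matter region itself were higher in the striatal spots by 0.276 (95% interval over slides 0.0602 to 0.492), and the white-matter share of spots was given above.

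Camera with the preset correlation also called 4 lists whose calls were likewise lost, each with adjusted p = 0.79 with an estimated correlation. Nuclear genes of the respiratory chain lay lower (31 of 34 members below 0, median -0.06, 0 of them past the test, adjusted p = 4.9e-05), with Cox5a at -0.16 and Sdhb at -0.11. Blood cell genes lay higher (5 of 5 above 0, median 0.33, adjusted p = 0.015), as did activated microglia (14 of 14 above 0, median 0.07, adjusted p = 0.036) and astrocytes (15 of 17 above 0, median 0.05, adjusted p = 0.036). Mt2 was the only member of these 4 lists past the test, and 2 members of the astrocyte list, Mt2 and Mt1, rose adjusted over the list alone. Fry called 1 list, the immediate early genes.

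Lists for the 2 classes of projection neuron were not called. The indirect-pathway list had a median of 0.03 over 9 genes (adjusted p = 0.51) and the direct-pathway list -0.04 over 9 genes (adjusted p = 0.55) by camera. Adjusted over the list alone, 2 indirect-pathway genes rose, Ptprm (0.20) and Adora2a (0.14), and 0 direct-pathway genes passed edgeR's test (54 calls over all genes, 1608 at an unadjusted p under 0.05). Genes of dopamine synthesis and transport had a median of 0.01 over 7 measured genes and a mean of -0.02, with a camera adjusted p of 0.99.

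**Figure D3:**
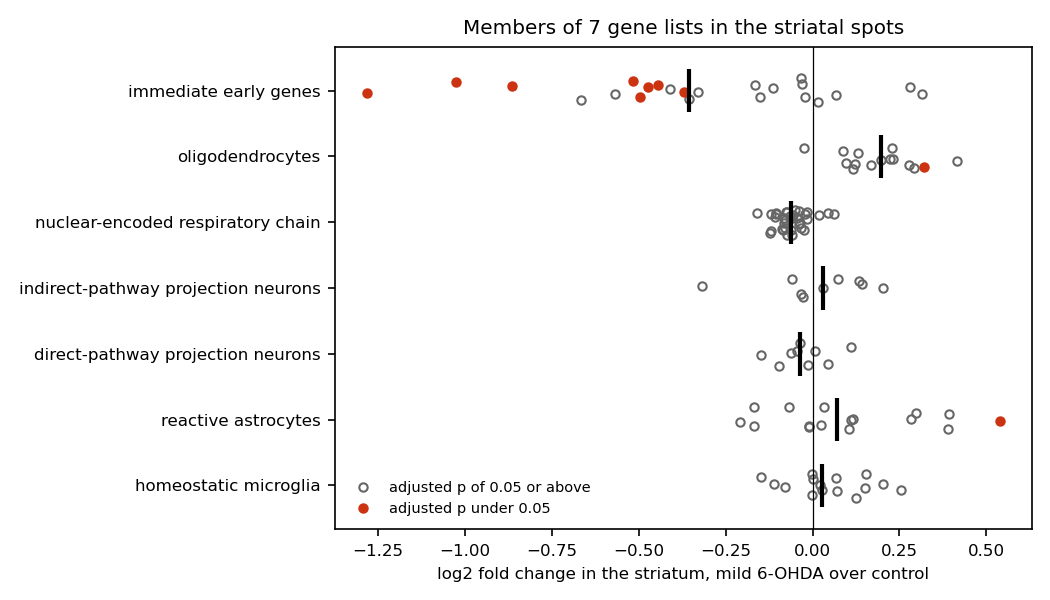
Log2 fold changes of the members of 7 gene lists in the striatal spots, 6-OHDA over control; each circle is a gene, filled where its adjusted p is under 0.05, and each bar is the list's median. The immediate early genes have a median of -0.36 and the oligodendrocyte genes of 0.20, and the other 5 medians lie between -0.06 and 0.07.

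In the cortex, which lies outside the main target of nigrostriatal dopamine axons, the genes with the largest decreases by the same rule were again immediate early genes. Nr4a1 fell by 1.28 (standard error 0.14), from 83.1 ± 15.8 to 36.0 ± 18.1 CPM (n = 12 each). Arc fell by 1.18, from 104 ± 44.2 to 51.3 ± 34.8 CPM, Fos by 0.85, the phosphatase gene Dusp1 by 0.85 and Junb, a partner in AP-1, by 0.69, and Egr1 fell by 0.44. Each was lower on all 6 slides, and the fall was largest in slide pair 3: the log2 differences of slide pairs 1 to 3 were -0.72, -0.54 and -2.45 for Arc, -0.43, -0.33 and -1.999 for Fos and -0.53, -0.54 and -1.52 for Dusp1. The genes that rose changed less: Dact2, which acts on Wnt signalling (0.34), the ubiquitin protease gene Usp2 (0.27), Gabrg3, a subunit of GABA-A receptors (0.26), Arhgap42 (0.26), and Rasgef1b, which activates Ras family GTPases (0.26).

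In all, 140 of 13925 cortical genes passed edgeR's quasi-likelihood test, 41 higher and 99 lower. As above, sections share animals and these p-values are too small. With 3 sums against 3 the count was 0 (edgeR, 729 at an unadjusted p under 0.05) and with the slide pair as a block 26; without slides 1 to 6 it was 50, 345, 50, 72, 123 and 83, and without the 4 sections rich in spots of few UMIs 39.

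**Figure D4:**
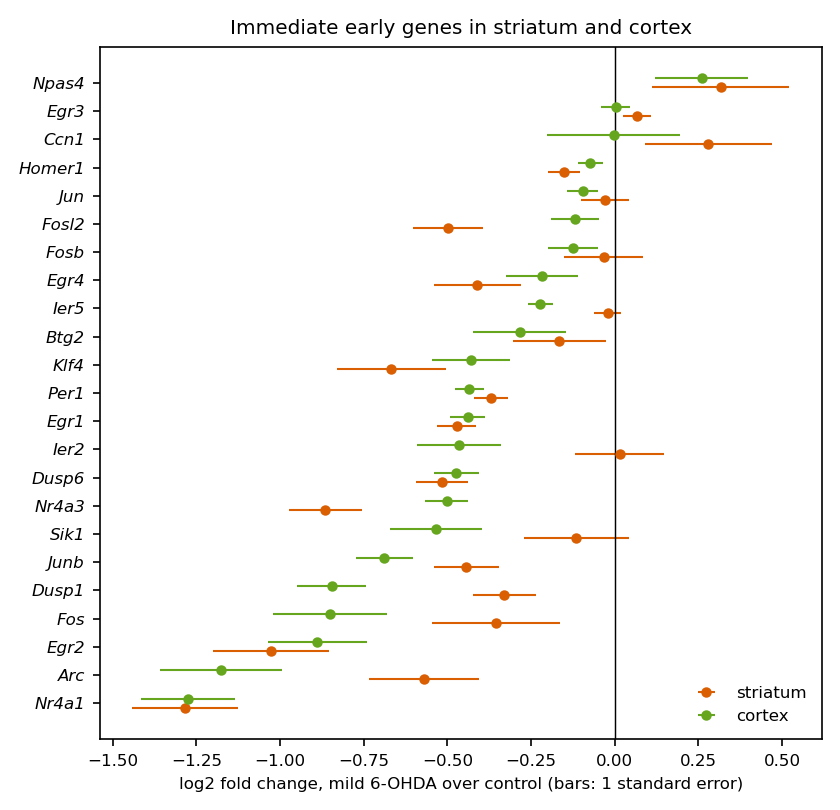
Log2 fold change of the 23 immediate early genes in striatum (orange) and cortex (green), 6-OHDA over control, with bars of 1 standard error (n = 12 sections per group). Nr4a1 lies at -1.28 in both regions, and Arc and Dusp1 lie lower in the cortex.

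Of the 23 immediate early genes, 11 fell in the cortex and 14 adjusted over the list alone, with a median of -0.43 and adjusted p = 0.0068 with an estimated correlation. Camera with the preset correlation called 10 of the 35 lists there, and the other 9 calls were lost with an estimated correlation. Fry called 3, the immediate early genes (adjusted p = 2.3e-05), potassium channels (0.0068) and GABA synthesis and receptors (0.030). Potassium channel genes lay higher (20 of 23 above 0, adjusted p = 0.071 with an estimated correlation). Glutamate receptor and postsynaptic genes had Grin2a (0.17) and Grin2b (0.20), subunits of NMDA receptors, past the test, with adjusted p = 0.255 for the list with an estimated correlation. GABA synthesis and receptor genes (Gabrg3 past the test, adjusted p = 0.204 with an estimated correlation) also lay higher, as did the indirect-pathway list as a whole (5 of 7 above 0, 0 past the test by edgeR, median 0.22, adjusted p = 0.229 with an estimated correlation). Nuclear respiratory chain genes lay lower (33 of 34, median -0.07, adjusted p = 0.815 with an estimated correlation), as did ribosomal protein genes (26 of 32, median -0.07, adjusted p = 0.835 with an estimated correlation) and chaperones (13 of 17, median -0.03, adjusted p = 0.600 with an estimated correlation). Oligodendrocyte genes (13 of 15 above 0, median 0.10, adjusted p = 0.835 with an estimated correlation) and nuclear transcripts, a measure of RNA quality (6 of 6 above 0, median 0.0615, adjusted p = 0.600 with an estimated correlation), lay higher.

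Within the striatum, the dorsal part gave 132 called genes of 12496, 66 in each direction. Nr4a1 fell by 1.45 (standard error 0.15), from 83.1 ± 25.0 to 32.0 ± 21.0 CPM (n = 12 each), Tiparp by 0.74, Dusp6 by 0.59, Egr1 by 0.53 and Junb by 0.51, and Arc fell by 0.63, lower on 5 of 6 slides, with -0.47, 0.06 and -1.60 in slide pairs 1 to 3. Rasl11b rose by 0.69 (standard error 0.09), C4b, a complement component, by 0.64, from 9.71 ± 3.05 to 15.5 ± 3.37 CPM (its near-identical copy C4a could share reads with it), Ttyh2 by 0.43, Sun2, a protein of the nuclear envelope, by 0.41, and the cyclin gene Ccno by 0.40. Of 22 immediate early genes 13 fell (14 adjusted over the list alone, median -0.45, adjusted p = 0.0033 with an estimated correlation). Vim, an intermediate filament of reactive astrocytes, rose by 0.37 (standard error 0.09). Camera with the preset correlation called the list of reactive astrocytes (9 of 15 above 0, median 0.11, adjusted p = 0.047). That call was lost with an estimated correlation (adjusted p = 0.238). Fry did not call the list (adjusted p = 0.052), while its test for changes in either direction gave an adjusted p of 3.4e-05. The same limits on p-values hold here, with 0 genes for 3 sums against 3 (edgeR, 680 at an unadjusted p under 0.05), 55 with the slide pair as a block, 27 without the 4 sections rich in spots of few UMIs, and 61, 196, 34, 47, 88 and 161 without slides 1 to 6, of which 30, 94, 11, 16, 55 and 98 were higher.

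Fewer sections carried a ventral striatum, 7 control and 8 6-OHDA, and no gene was called there. Egr1 stood at 151 ± 41.6 CPM in control (SD, n = 7) and 118 ± 29.9 CPM in 6-OHDA sections (SD, n = 8), a log2 difference of -0.25 (standard error 0.11), Nr4a1 had -0.33 (standard error 0.20) and Nr4a3 had -0.58 (standard error 0.17), below 0 on all 4 slides, and Gfap had -0.41 (standard error 0.20). Fos had 0.20 (standard error 0.27). Of 18 immediate early genes measured there 12 lay below 0 and 6 above, with a median of -0.07. Camera did not call the list (adjusted p = 0.103, or 0.773 with an estimated correlation). Nuclear respiratory chain genes lay lower (33 of 34, median -0.11), with a camera adjusted p of 7.0e-14 with the preset correlation and 0.478 with an estimated correlation. The preset correlation also called GABA synthesis and receptors (16 of 18 above 0, adjusted p = 0.011) and the indirect-pathway list (8 of 8 above 0, 0.025). Clock and glucocorticoid genes (9 of 13 above 0, 0.028) were called too. With an estimated correlation no list was called. No gene of 10978 passed edgeR's quasi-likelihood test over these sections, of which several share an animal (547 at an unadjusted p under 0.05); DESeq2 and limma voom with the slide as a random block called 0 as well, and 3 sums against 3 called 0, or 3 with the slide pair as a block.

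White matter also gave no called gene, at a lower depth, from 198552 to 2292571 UMIs per section. Nr4a1 had a log2 difference of -0.64 (standard error 0.17), Arc -0.42 (standard error 0.12) and Gfap -0.23 (standard error 0.08), with Gfap at 291 ± 49.6 CPM in control and 247 ± 32.3 CPM in 6-OHDA sections. Of 11 immediate early genes measured there 8 lay below 0 and 3 above, with a median of -0.04. Camera did not call the list (adjusted p = 0.062, or 0.515 with an estimated correlation). Mitochondrially encoded genes lay higher (12 of 13, median 0.07), with a camera adjusted p of 0.00012 with the preset correlation and 0.491 with an estimated correlation. In all, the preset correlation called 6 lists there and an estimated correlation called none. Among the 6 were the indirect-pathway (5 of 5 above 0, adjusted p = 0.034) and direct-pathway lists (4 of 4 above 0, 0.041). None of 8070 genes passed edgeR's quasi-likelihood test over sections, which share animals (477 at an unadjusted p under 0.05); limma voom with the slide as a random block called 0 and DESeq2 2. With the replicate number as a block, which pairs same-numbered sections, edgeR called 3, and 3 sums against 3 called 0, or 4 with the slide pair as a block.

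Over whole sections, which depend on no region assignment but on where the brain was cut, Nr4a1 fell by 1.16 (standard error 0.14), Dusp5 by 0.59, Dusp1 by 0.58, Nr4a3 by 0.53 and Tiparp by 0.47, while Dact2 rose by 0.33, Rasgef1b by 0.30, Usp2 by 0.29, and Rasl11b and Frat1 by 0.27. Fos (-0.70) and Arc (-0.91) also passed, each lower on 5 of 6 slides and most so in slide pair 3 (-0.45, -0.00147 and -1.68 in slide pairs 1 to 3 for Fos, -0.60, -0.20 and -1.93 for Arc). In all, 162 of 15365 genes were called by edgeR's quasi-likelihood test, 52 higher and 110 lower, over sections that share animals. The sums give little of this: 3 against 3 called 0 genes (edgeR, 848 at an unadjusted p under 0.05), and 0 with the slide pair as a block (2334 at an unadjusted p under 0.05), while 6 sums per group by slide called 3. Without slides 1 to 6 the count was 35, 516, 29, 42, 46 and 158, of which 9, 174, 8, 11, 17 and 91 were higher, and without the 4 sections rich in spots of few UMIs 24.

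Striatum and cortex were compared directly by the treatment by region interaction. Arc and Dusp1, 2 immediate early genes, fell less in the striatum than in the cortex, with interaction values of 0.55 (standard error 0.10, edgeR adjusted p = 0.0257) and 0.49 (standard error 0.08, edgeR adjusted p = 0.0151), on all 6 slides. Nr4a1 and Egr1, which fell in both regions, were not called, with interactions of -0.02 (standard error 0.12) and -0.03 (standard error 0.06). Arc and Dusp1 were the 2 called genes of 14258 (Benjamini-Hochberg, 798 at an unadjusted p under 0.05), in sections that share animals. With 3 sums per group the count was also 2, with none of these genes among them. It was 0 without slide 4, slide 5 or slide 6, and limma voom on the difference between regions with the replicate number as a block called 35, which included both. Camera with the preset correlation called lists in both directions. Ribosomal proteins (adjusted p = 1.8e-05), homeostatic and activated microglia (0.00016 each), reactive astrocytes (0.00045) and oligodendrocytes (0.0065) were among those whose change lay higher in the striatum. Presynaptic vesicle genes (0.026) and potassium channels (0.043) lay lower. With an estimated correlation no list was called (smallest adjusted p = 0.115).

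Fold changes of the 12703 genes tested in both regions correlated at r = 0.464 across genes, which are not independent replicates. Both regions came from the same sections, so a correlation arises without any effect: over 59 other splits of the sections its median was 0.298 and its maximum 0.503, and the covariance was 0.00581 against a median of 0.00229 and a maximum of 0.00514. When striatal changes came from 1 slide pair and cortical changes from the other slide pairs, r was 0.0753, 0.175 and 0.169 and the covariance 0.00170, 0.00385 and 0.00365. Of the genes called in both regions 16 were lower and 4 higher, where independent lists of these sizes would share 0.220 and 0.0661; neither value allows for the shared sections.

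Dorsal and ventral striatum differed for 3 genes of 12507. The change of Nr4a1 lay lower in the dorsal than in the ventral part (interaction -0.84, standard error 0.13, edgeR adjusted p = 0.00045), as did that of Rgs2 (-0.45, standard error 0.08, edgeR adjusted p = 0.0108), while that of Ptgds lay higher (0.48, standard error 0.08, edgeR adjusted p = 0.0012), each with 1 sign on all 4 slides. The immediate early genes as a list lay lower in the dorsal part (16 of 23 below 0, median -0.27). Camera with the preset correlation called the list (adjusted p = 6.3e-08), a call lost with an estimated correlation (adjusted p = 0.19). At an unadjusted p under 0.05 there were 610 genes, and the sections share animals. With 3 sums per group the count was 2, 1 of them shared. It was 0 without slide 5, 5 without slide 2 and 2 without slide 3, and limma voom with the replicate number as a block called 16, which included all 3.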

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

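Of the tests in this part, those of the immediate early genes against the cortex, over slide pairs, at equal mitochondrial share and without the 4 most deviating sections of a group were chosen only after the result was seen. Of the genes below, Arc, Dusp1 and Nr4a1 belong to the immediate early genes, and each changed differently in 2 parts of the same sections by the interaction test. Arc and Dusp1 fell less in the striatum than in the cortex (0.55 and 0.49 on the log2 scale), and in the dorsal against the ventral striatum Nr4a1 (-0.84) and Rgs2 (-0.45) lay lower and Ptgds (0.48) higher. Groups were exchanged between control and 6-OHDA sections of the same number to see what other splits give; the number of splits was cut from 60 to 40 for time after a first run had been seen. For striatum against cortex, 1 of 40 splits, the real one, gave as many genes (2, against 1 at most in the others). This argues against chance only as defined by these splits, and on a count of 2. The splits mix sections of different animals and do not speak to differences between animals. The count was 0 without slide 4, slide 5 or slide 6, and 3 sums per group called 2 genes, 0 of them shared. For dorsal against ventral striatum 3 of 40 splits gave as many (3, against 4 at most), so chance cannot be excluded. No section stood apart from its group in the tests of single outlying values.

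The immediate early genes were lower in the 6-OHDA sections in striatum and cortex. Lower depth in the 6-OHDA sections is argued against for the striatum: in striatal sums thinned to equal totals the list's median was -0.366 (95% interval over slides -0.557 to -0.176). So is a larger mitochondrial share of the striatal UMIs: at an equal share the list's level differed by -0.353 (95% interval over sections -0.468 to -0.239), against -0.357 without that adjustment. One deviating slide pair is argued against too, because with each left out in turn the highest mean over the other 4 slides was -0.279 (-0.550 to -0.00789) in the striatum and -0.292 (-0.453 to -0.130) in the cortex, where slide pair 3 fell most. One deviating animal, taken as any 4 sections of a group, is argued against as the only source. Without the 4 lowest 6-OHDA sections the striatal difference was -0.2285 (-0.414 to -0.0426), and without the 4 highest control sections -0.227 (-0.382 to -0.0709). The smaller of these 2 differences in the cortex was -0.272 (-0.455 to -0.0889). These are differences of plain group means, without the slide as a covariate. In the striatum the 4 highest control sections were all the controls of slides 1 and 2. These intervals are over sections that share animals and so are too narrow, and differences between several animals were not tested. Handling or collection of the animals that acted on the whole section may account for it, since the cortical median of -0.409 (-0.617 to -0.201) was no smaller than the striatal -0.320. White matter and the ventral striatum had fewer UMIs per section and fewer of the list's genes measured. The list's median log2 fold change was less low there. It was -0.04 in white matter (8 of 11 genes below 0) and -0.07 in the ventral striatum (12 of 18 below 0). Camera called the list in neither region. Within sections, the list's change lay lower in the dorsal than in the ventral striatum (16 of 23 genes below 0, median -0.27). Camera gave this difference an adjusted p of 6.3e-08 with the preset correlation and 0.19 with an estimated correlation. An effect of the lesion that reaches the cortex predicts the cortical fall as well, and, as the controls were untreated, so does the injection itself. The effects of lesion and injection were not tested. Collection at another time of day cannot be told apart, because the difference between clock genes of opposite phase in the cortex, -0.000568, has an interval from -0.158 to 0.157. In the striatum it was 0.0838 (-0.0931 to 0.261). Single clock genes moved in both directions in the cortex. Per2 fell by 0.38 (edgeR adjusted p = 0.0207) and Per1 by 0.43, while Nr1d1 (0.12) and Dbp (0.06) lay higher without a call.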

How the results depend on the processing

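Of the tests in this part, those with the slide pair within group as a random block, without the sections rich in spots of few UMIs, and of lists in other regions were chosen after the data were seen. The counts of called genes depended strongly on how sections were treated as samples and on single slides, and the cause was not tested except where named. In the striatum (54 genes) the count was 9 without any block, 0 for 3 sums against 3 (569 at an unadjusted p under 0.05) and 22 with the slide pair as a block, 26 for sums per slide, 115 by DESeq2, 264 without a low-count filter, 35 at a mean of at least 10 CPM (fewer genes were tested), 22 in the spots with the lowest white-matter share, 14 in thinned sums, 14 without the 4 sections rich in spots of few UMIs (fewer sections), and 20 (without slide 3) to 137 (without slide 2) with 1 slide left out. Random blocks of slide pair within group gave 301 genes with the slide as a covariate, where the estimated correlation was negative (-0.0663), and 4 with treatment only (correlation 0.0526). The other settings gave 46 to 62 genes. The left-right asymmetry of the striatum and its 2 other settings, interior spots and all genes at a mean of at least 50 CPM, were not computed, because each section held 1 hemisphere.

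In the cortex (140) the same settings gave 34 without any block, 0 and 26 for 3 sums against 3, 39 for sums per slide, 215 by DESeq2, 588 without a filter, 222 and 15 with the 2 random blocks (correlations -0.0215 and 0.108), 39 without those 4 sections and 50 to 345 with 1 slide left out. In the dorsal striatum (132) they gave 20, 0 and 55, 84, 334 without a filter, 349 and 12 (correlations -0.0504 and 0.0813), 27 and 34 to 196. In the whole section (162) they gave 9, 0 and 0, 3, 479 by DESeq2, 314 without a filter, 665 and 0 (correlations -0.0585 and 0.0738), 24 and 29 to 516. White matter (0 by edgeR, 477 at an unadjusted p under 0.05) gave 3 with the replicate block, 4 for 3 sums against 3 with the slide pair as a block, 4 for sums per slide, 2 by DESeq2, 23 without a filter and 9 with the slide as a covariate and a random block. The ventral striatum (0 by edgeR, 547) gave 3 for 3 sums against 3 with the slide pair as a block, 13 without a filter, 1 at a mean of at least 10 CPM and 1 with the slide as a covariate and a random block. Striatum against cortex (2) ranged from 0 to 3 and dorsal against ventral striatum (3) from 0 to 5 with 1 slide left out, and the replicate block gave 35 and 16. The replicate block moved no other count by over 1.5 times. Lists called in the striatum (6) numbered 1 with an estimated correlation, 1 by fry, 10 in the cortex and 3 to 9 with 1 slide left out.

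Of the 30 named striatal genes none past the threshold changed sign in any setting except Megf10, at -0.0537 in thinned sums; Nr4a1 ranged from -1.47 to -1.11 and Egr1 from -0.54 to -0.41, both losing their call for 3 sums against 3 and Egr1 also with treatment only and a random block. Most genes that rose lost their call, with the sign kept, in more settings: Ptgds and Megf10 in 16 settings each, Tspan2 in 13, Kndc1, Sox12 and Tmem88b in 12, Mt2 in 11, Arrdc3 in 10, Gprc5b in 8 and Rasl11b in 4, of 26 or 27. Among the genes that fell Fosl2 lost it in 11, and the others in 1 to 3. Arc and Fos, not past the threshold, gained a call in 2 settings and in 1, with the sign kept throughout. Genes near 0 changed sign without a call. For Th in the striatum, log2 fold change 0.01, the value was -0.0555 for 3 sums against 3, -0.0570 with the slide pair as a block, -0.0069 for sums per slide, -0.0519 with the slide as a random block, -0.0159 in gated spots, -0.0413 and -0.0601 with the added random blocks, -0.0798 without those 4 sections and -0.0521 to 0.0793 with 1 slide left out. For Pdyn in the striatum, log2 fold change -0.04, it was 0.0074 with the slide pair as a block, 0.0113 in the spots with little white matter, 0.0505 without those 4 sections and -0.142 to 0.0821 with 1 slide left out. For Gfap in the striatum, log2 fold change 0.02, it was -0.0138 for sums per slide, -0.0872 without those 4 sections and -0.0651 to 0.113 with 1 slide left out. In thinned sums Drd2 was -0.0014 and Drd1 -0.00056. With 1 slide left out, the difference between groups ranged from -235.7 to 684.0 for striatal UMIs per spot (section median), from -68.1 to 122.8 for striatal genes per spot (section median), from -0.109 to 0.541 for the striatal mitochondrial share in percent (section median), from -1.36 to 2.62 for the striatal share of spots in percent, and from -1.82 to 0.509 for the cortical share of spots in percent. The striatal share differed by 0.316 when spots were gated. Depth limits the smallest changes: the ventral striatum and white matter had the fewest UMIs per section, from 621484 and 198552.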

Other observations

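Of the tests in this part, the comparison of lists with the cortex and the use of the spots with little white matter for lists were added after the data were seen, but before their own results were. Immune genes in the striatum were examined as 2 further lists. Of 11 measured genes of complement, antigen presentation and interferon, C4b rose by 0.54 (standard error 0.10) and Ifit3, an interferon-induced gene, by 0.52 (standard error 0.11); 3 members rose adjusted over the list alone. Both genes have near-identical copies that could share reads with them. Of 16 genes of reactive astrocytes, C4b rose, and Vim (0.28, standard error 0.08), Serpina3n (0.39, standard error 0.15) and Osmr (0.39, standard error 0.16) did not pass edgeR's quasi-likelihood test over all genes. Over all striatal spots, camera called neither list (adjusted p = 0.29 and 0.19). Fry's test for changes in either direction gave an adjusted p of 0.0033 for both. In the dorsal striatum camera called the reactive astrocytes with the preset correlation only, as given above.

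Clock and glucocorticoid genes moved in both directions in the striatum, Per1 (-0.37) falling and Mt2 (0.37) rising, with Nr1d1 at 0.23 (standard error 0.07) and Bhlhe41 at 0.17 (standard error 0.05); adjusted over the list alone 3 of 13 rose and 2 fell. Among chaperones, Dnaja1 stood at -0.14 (standard error 0.04) in the striatum and fell adjusted over the list alone.

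Other splits of the sections, made by exchanging the groups within same-numbered pairs of sections, bear on each count. For the striatum 1 of 60 splits, the real one, gave as many genes (54, against 1 at most in the others). The same held for the cortex (1 of 60, 140 against 1), the dorsal striatum (1 of 60, 132 against 1) and the whole section (1 of 60, 162 against 1). For these 4 this argues against chance only as defined by these splits. These splits mix sections of different animals and do not speak to differences between animals. For the white matter and the ventral striatum, with 0 genes by edgeR (477 and 547 at an unadjusted p under 0.05), all 60 of 60 splits give as many whatever the data, with 3 and 4 at most in the others, so the splits say nothing about chance there. The groups of whole slide pairs can be exchanged in only 4 splits, too few for a share under 0.05: 1 of 4 gave as many genes in the striatum (54, against 4 at most) and 1 of 4 in the cortex (140, against 24 at most). For the count of called lists in the striatum, 15 of 60 splits gave 6 or more (10 at most in the others), so chance cannot be excluded. List by list, 1 of 60 splits gave a camera p as small as the real one for the immediate early genes (1.4e-15, against 2.0e-14), 7 for the oligodendrocytes and 17 for the nuclear respiratory chain.

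Oligodendrocyte genes lay higher in the striatal spots of the 6-OHDA sections, and no explanation is settled. More white matter within those spots may account for it and cannot be told apart: in the spots with the lowest white-matter marker share the list's median was 0.181 (95% interval over slides -0.0042 to 0.367), against 0.196 in all striatal spots. Markers of white matter were as much higher in these spots, by 0.3004 (0.0464 to 0.554), as in all striatal spots (0.276), so the choice of spots did not remove the difference it was meant to remove. A change over the whole section cannot be told apart either, because the cortical median of 0.0654 has an interval from -0.0942 to 0.225. Camera with the preset correlation called the list there (adjusted p = 0.046), a call lost with an estimated correlation (adjusted p = 0.835). The list was called neither in white matter (7 of 15 genes above 0, median -0.01) nor in the ventral striatum (7 of 14 above 0, median -0.006). In the dorsal striatum (median 0.23) camera called it with the preset correlation (adjusted p = 3.35e-09), as did fry (0.046). That call was lost with an estimated correlation (0.238). The list's change lay higher in the striatum than in the cortex (15 of 15 above 0) and in the dorsal than in the ventral part (14 of 15). Camera's adjusted p for these differences was 0.0065 and 6.2e-07 with the preset correlation, and 0.69 and 0.22 with an estimated correlation. A change of oligodendrocytes in the striatum of the 6-OHDA sections stays open and was not tested.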
